A study of Mus musculus with 8 samples.

How the data were processed

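Total RNA of 8 samples of large T antigen-immortalized mouse embryonic fibroblasts was measured, 2 each of wild type, FIH null, VHL null and VHL/FIH null (double null) cells cultured at 21% oxygen. The RNA was purified on columns with digestion of DNA and hybridized to Affymetrix Mouse Genome arrays by the standard protocol of the maker. The values deposited by the authors are MAS5 signals, a linear intensity per probe set and array, made with MAS5 per the submitters' processing notes, whose version the sources used here do not give. The deposited table holds 45101 probe sets, 64 of them controls. Each array's trimmed mean, with 2% left off each end, was 2500.01, and these differed by 5.02e-05 percent, so the values were used as deposited without further normalization. Median signals of the arrays ran from 281.5 to 307.1. Ratios of 3' to 5' control probe sets ran from 1.20 to 1.27 for Actb and from 0.794 to 0.811 for Gapdh between groups.

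Signals were transformed to log2 after adding a pseudocount of 16. A probe set was tested if its signal was above 291.1, the median of all signals, on at least 2 arrays, which left 24523. Probe sets were assigned to genes by the platform's annotation table, with symbols updated through Entrez gene numbers: 34945 had 1 symbol, 932 had several and 9160 had none or were not listed, and only the first kind was used for genes. Of 18193 genes with a probe set 11564 were tested, each by its tested probe set with the highest mean log2 signal, and 5798 of these had more than 1 tested probe set. Chromosomes were taken from a gene table of the mouse genome, which placed 11538 genes. The 2835 tested probe sets without a single symbol were counted apart: 90 changed between FIH null and wild type, 720 between VHL null and wild type, 696 between double null and wild type, 609 between double null and VHL null, 780 between double null and FIH null, and 286 had an interaction.

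Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean signal, prior degrees of freedom 7.04, residual degrees of freedom 4), and 6 contrasts were tested, 5 between pairs of groups and the interaction. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes of each comparison, with a threshold of 0.05. All p-values measure only the spread between these samples, which the labels call biological replicates without saying whether they are separate embryos or cultures. Overlaps of comparisons that share no array, but share the estimate of each gene's spread, were set against the number expected of independent lists. A match of replicates by number was not found: differences between replicates correlated between groups with r from 0.00869 to 0.0393 over 6 pairs of groups.

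The gene lists, the comparisons, the tests, most alternative settings and the rule for named genes were set before the data were examined. There were 27 lists with 694 entries, 647 of them with a probe set and 544 tested: HIF pathway components, glucose uptake and glycolysis, other hypoxia-inducible genes, oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, fatty acid and cholesterol synthesis, the Notch pathway, NF-kB targets and inhibitors, interferon-stimulated genes, extracellular matrix, matrix remodelling enzymes, contractile and myofibroblast genes, cell cycle and DNA replication, p53 targets, amino acid deprivation and ER stress genes, NRF2 targets, Hox genes, imprinted genes, sex-linked genes, and markers of macrophages, endothelium, adipocytes, skeletal muscle, epithelium, neural cells and cartilage or bone. The 25 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Of 36 list results that passed, 3 held with a correlation estimated from the data, those of fatty acid and cholesterol synthesis in VHL null and double null cells against wild type and in double null against FIH null cells. The self-contained test fry was run as another alternative, and it asks only whether the genes of a list move on balance one way.

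Named genes were chosen by rule. For each comparison they were Hif1an and Vhl, the 6 largest rises and the 6 largest falls that passed with no overlap between the arrays of the groups, up to 4 members with the smallest p of each list that passed, 4 members of the glycolysis and hypoxia lists in every comparison, and the sex-linked genes. For the overlaps they were the 6 largest mean changes per direction.

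Alternatives were a pseudocount of 1 or 64, no filter, a filter at the 75th percentile of signals (2454), quantile normalization, centring each array's median, no variance trend, array weights, only the compared groups, the mean of a gene's probe sets, leaving out probe sets that may cross-hybridize, the replicate number as a block, leaving out each array in turn, a change of at least 2-fold, and for lists an estimated correlation and fry. A larger pseudocount, scaling to the hybridization controls and centring each chromosome's median were added after seeing the data. The fit was tested on simulated data with 200 planted changes among 11564 genes. At a planted log2 change of 1 it recovered 78.8% of them for VHL null against wild type, 77.3% for FIH null against wild type, 83.3% for double null against VHL null and 72.7% for the interaction, and 3.68%, 6.67%, 4.79% and 4.96% of its calls were false. A planted shift of -0.5 in 1 list was called and 0 of the other lists were. The simulated genes varied independently, so this run could not show false calls among lists whose members move together. In the data the estimated correlation reached 0.533, for glycolysis genes. With 2 arrays per group, other splits of the samples and outlying arrays within a group were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.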

Results

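Gene expression was measured on Affymetrix Mouse Genome arrays in large T antigen-immortalized mouse embryonic fibroblasts (MEFs), cells grown out of embryos and kept dividing by a viral oncoprotein. The cells were cultured at 21% oxygen, and each of 4 groups held 2 arrays. The groups were wild type, FIH null, VHL null and VHL/FIH null, called double null here. The null cells were made by infecting cells with floxed alleles with an adenovirus that carries Cre recombinase. FIH, encoded by Hif1an, is an asparaginyl hydroxylase that limits transcription driven by the hypoxia-inducible factors (HIF), and VHL is the part of a ubiquitin ligase that marks HIF alpha subunits for destruction. By the design text each null group came from its own floxed line, so that genotype and line of origin coincided in these 8 arrays. The number of arrays limits the precision of every value.

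Across probe sets, which are not independent replicates, arrays of the same group correlated with r = 0.989 in each of 4 pairs, and arrays of different groups with r between 0.942 and 0.976 in 24 pairs. Every array had a trimmed mean of 2500.01, so a change is relative to its array's mean level. Spiked hybridization controls exceeded wild type by 0.26 on the log2 scale in FIH null, 0.38 in VHL null and 0.52 in double null arrays. Scaling to these controls, chosen after seeing the data, moves all genes down by those amounts. Whether the controls track RNA per cell was not tested, so this shows only dependence on scale. The 18S ribosomal RNA control read 552 ± 45.0 in wild type, 539 ± 114 in FIH null, 1263 ± 138 in VHL null and 1021 ± 14.6 in double null arrays.

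Signals are the mean ± SD of the 2 arrays of a group, and changes are differences of group means on the log2 scale with limma adjusted p-values. A gene with a group below the signal cutoff of 291.1 is given with an "at least" fold, the other group's signal divided by 291.1, because signals under the cutoff carry little information on level. List members that passed are named where 5 or fewer did, and those outside the rule for named genes were chosen after their values were seen. Of 18193 genes with a probe set, 11564 were tested. Genes called top rises or falls below are the first by log2 difference, an order that is not a measure of size where a group lies below the cutoff, so that other genes may have changed more. For each top rise or fall between a pair of groups, the 2 arrays of one group did not overlap the 2 of the other, which chance gives for 33.3% of genes.

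The first question was whether the deleted genes' own transcripts were reduced. Hif1an signal was 2867 ± 206 in wild type, 1691 ± 21.7 in FIH null, 2033 ± 169.9 in VHL null and 1286 ± 166 in double null cells. Against wild type it fell by 0.75 on the log2 scale in FIH null cells (SE 0.118, adjusted p = 0.00271) and by 1.15 in double null cells (adjusted p = 2.04e-05). It also fell by 0.49 in VHL null cells, where FIH was not targeted (adjusted p = 0.00597). The call in VHL null cells ended with the mean of its probe sets (adjusted p = 0.564), without wild type replicate 2 (adjusted p = 0.053) and without VHL null replicate 1 (adjusted p = 0.0558). Vhl signal was 3294 ± 36.0 in wild type, 3479.7 ± 76.5 in FIH null, 731 ± 33.2 in VHL null and 979 ± 116 in double null cells. Vhl fell by 2.15 in VHL null cells (SE 0.112, adjusted p = 1.84e-07) and by 1.74 in double null cells (adjusted p = 5.17e-07), and its log2 change of 0.08 in FIH null cells did not pass the test (adjusted p = 0.735). The labels do not give the deleted exons, so a probe set outside the deleted part would not read the deletion, and the remaining signal is not a measure of the protein.

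**Figure D1:**
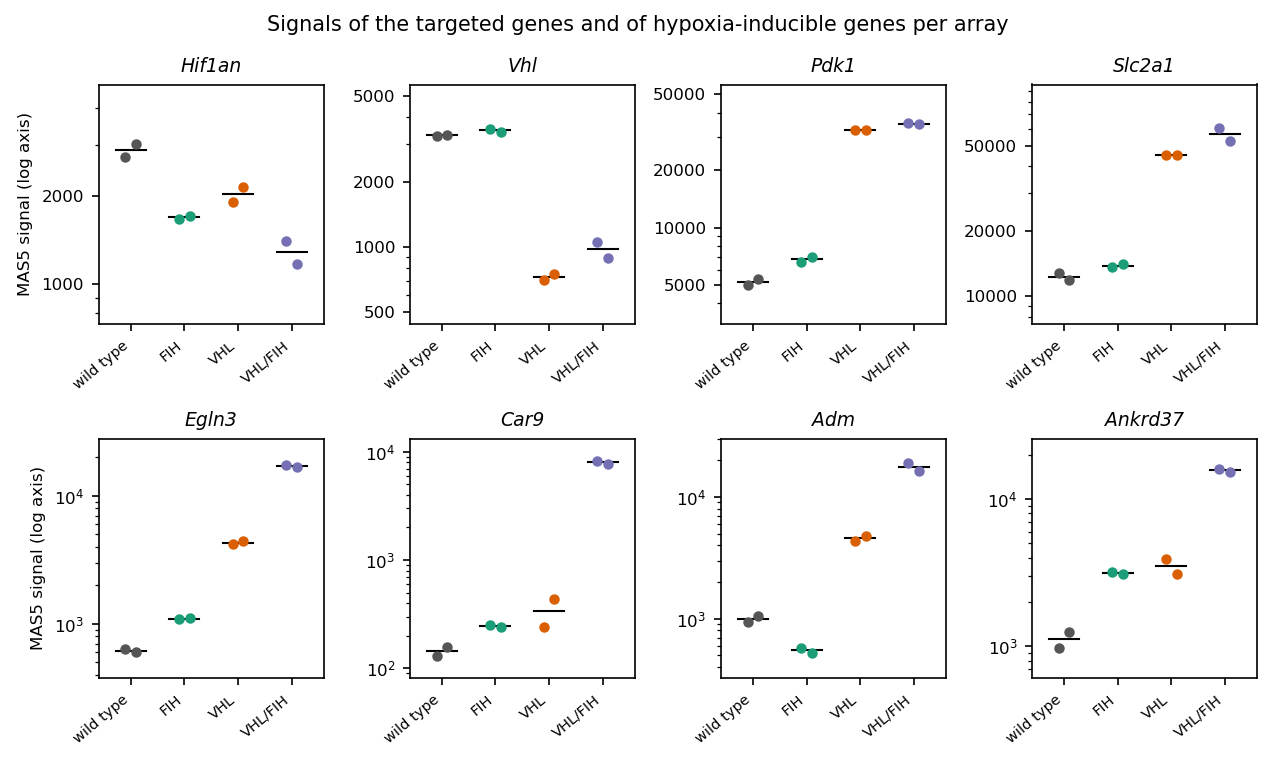
MAS5 signal of each array (points, log axis, intensity units) and group mean (dash) for Hif1an, Vhl and 6 hypoxia-inducible genes in wild type, FIH null, VHL null and double null cells. Pdk1 and Slc2a1 were high in both groups without VHL, while Car9 was at 339 in VHL null and 8026 in double null cells.

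VHL null cells were compared with wild type cells. Most tested genes of glucose use and of the hypoxia response were higher and those of lipid synthesis were lower in VHL null cells. Of these lists only lipid synthesis passed with an estimated correlation. All of them passed with fry, which does not compare a list with other genes (largest fry adjusted p = 5.76e-04). The glucose transporter gene Slc2a1 read 12311 ± 640.4 in wild type and 45143 ± 217 in VHL null cells. Pdk1, whose kinase keeps pyruvate out of the citric acid cycle, read 5185 ± 273 and 32524 ± 85.1. The lipoprotein receptor gene Vldlr rose from 1491 ± 69.4 to 20896 ± 869.7 (log2 change 3.79, adjusted p = 8.92e-10). Fdps, an enzyme of the cholesterol pathway, fell from 40679.8 ± 1059.6 to 16246 ± 1134 (log2 change -1.32, adjusted p = 1.02e-07).

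Of 34 tested hypoxia-inducible genes outside glycolysis, 29 rose and 0 fell in VHL null cells over all genes, and 29 rose and 1 fell adjusted over the list alone (mean log2 change 1.29, camera adjusted p = 1.84e-24; adjusted p = 0.265 with an estimated correlation). They included Tmem45a (3.87), Egln3, a HIF prolyl hydroxylase (2.77), and Bnip3, a mitophagy receptor (2.54). Among 19 genes of glucose uptake and glycolysis, 15 rose and 2 fell over all genes, and 16 rose and 2 fell adjusted over the list alone (mean 1.06, adjusted p = 8.88e-13; adjusted p = 0.424 with an estimated correlation). Pdk1 rose by 2.65, the phosphofructokinase gene Pfkp by 2.23, Slc2a1 by 1.87 and the hexokinase gene Hk2 by 1.79. The 2 that fell were Pfkfb4 (-0.45) and Eno2 (-0.68).

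All 28 tested genes of fatty acid and cholesterol synthesis fell in VHL null cells, over all genes and adjusted over the list alone (mean -0.81, adjusted p = 1.0e-15, and adjusted p = 0.0178 with an estimated correlation). Examples besides Fdps were the desaturase Fads2 (-1.21), the HMG-CoA synthase Hmgcs1 (-1.08) and the isomerase Idi1 (-1.0). Fatty acid oxidation genes were lower too. Of 23 there were 15 that fell and 2, Hadhb (0.50) and Slc25a20 (0.29), that rose over all genes, and 15 fell and 3 rose adjusted over the list alone (mean -0.26, adjusted p = 0.0293; adjusted p = 0.644 with an estimated correlation). Acadl (-0.52), Echs1 (-0.55) and Acadm (-0.38), enzymes of the oxidation spiral, were among those that fell. So was the carnitine transferase Cpt2 (-0.64), whose call ended with the mean of its probe sets (adjusted p = 0.142). The list's call ended with median centring (adjusted p = 0.0585), with the mean of probe sets (adjusted p = 0.0513) and without VHL null replicate 2 (adjusted p = 0.075).

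Of 59 oxidative phosphorylation genes in VHL null cells, 16 rose and 7 fell, over all genes and adjusted over the list alone. The list's mean was 0.08 (adjusted p = 9.23e-04; adjusted p = 0.644 with an estimated correlation). It turned to -0.04 with quantile normalization (adjusted p = 0.831) and to -0.30 with scaling to hybridization controls (0.279). The complex I subunit genes Ndufa1 (0.42) and Ndufa2 (0.38) and the cytochrome oxidase gene Cox5a (0.34) rose, calls that ended with scaling to hybridization controls, where Cox5a turned to -0.04. Sdha of complex II fell (log2 change -0.35), a call that ended with centring per chromosome (adjusted p = 0.0607). Of 24 interferon-stimulated genes, 12 fell and 0 rose over all genes and adjusted over the list alone (mean -0.82, adjusted p = 0.00264; adjusted p = 0.23 with an estimated correlation, and 0.0777 with scaling to hybridization controls). Rtp4 fell from 1216 ± 65.4 to 313 ± 29.9, and the antiviral tether gene Bst2 changed by -1.16 on the log2 scale. Ifit1, a sensor of viral RNA, went from 1212 ± 155 to 283 ± 68.8, at least 4.16-fold lower. Xaf1 was at least 3.15-fold lower.

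The top rises in VHL null cells were in genes below the cutoff in wild type cells, so their order is open. Among genes above it on all 4 arrays, Tmem45a and Vldlr rose most. Stc1, which encodes the hormone stanniocalcin, went from 159 ± 37.3 to 5061 ± 171, at least 17.4-fold higher, and 2610528A11Rik from 181 ± 2.90 to 4875 ± 361, at least 16.7-fold higher. Tafa2, a chemokine-like gene, was at least 7.44-fold higher, Ppp1r3b, which targets a phosphatase to glycogen, at least 3.93-fold, the neuropeptide gene Nmu at least 3.74-fold and Fam184b at least 2.22-fold, the last a call that ended without a filter on low signals (adjusted p = 0.385). Top falls were those of Pcdh17, a protocadherin (2778 ± 100.3 to 29.3 ± 26.7, at least 9.54-fold lower) and of the limb gene Hoxd13 (6615 ± 557 to 111 ± 11.6, at least 22.7-fold lower). The craniofacial homeobox gene Alx1 went from 1624 ± 89.3 to 41.0 ± 8.91, at least 5.58-fold lower. Enpep, which encodes an aminopeptidase, was at least 3.27-fold lower, and the neurotensin gene Nts at least 3.36-fold lower. Igfbp2, which encodes a binding protein of insulin-like growth factors, fell from 6099 ± 567 to 419.5 ± 17.8 (log2 change -3.81).

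In all, 5067 genes changed between VHL null and wild type cells (43.8% of those tested), 1788 higher and 3279 lower, and 627 of them changed at least 2-fold, 236 higher and 391 lower. The median change of all genes was -0.10, and scaled to hybridization controls 8406 genes passed, 5.16% of them higher. The larger share of falls turned with centring per chromosome (51.7% higher), which by construction brings each chromosome's median change near 0.

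FIH null cells were compared with wild type cells. Fewer genes changed, and the largest changes were falls. Zic1, a neural and skeletal patterning gene, went from 5914 ± 216 to 184 ± 7.07, at least 20.3-fold lower, and the cartilage collagen gene Col2a1 from 2161 ± 158 to 32.1 ± 11.4, at least 7.42-fold lower. Among hypoxia-inducible genes Ankrd37 rose from 1112 ± 195 to 3159 ± 67.4 (log2 change 1.5, adjusted p = 2.55e-05).

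Hox genes specify position along the body axis and limbs, and their list here includes Meis1, Meis2, Tbx4, Tbx5, Tbx15 and Pitx1. It held 10 genes of 31 that fell and 4 that rose in FIH null cells over all genes, and 12 that fell and 4 that rose adjusted over the list alone. The mean of the Hox list was -0.77 and its median -0.21 (adjusted p = 6.29e-04, 0.205 with an estimated correlation and 0.351 with scaling to hybridization controls). Members with signals below the cutoff enter the mean, so it is not a measure of size. Hoxb6 fell from 4306 ± 14.1 to 489 ± 23.6 and Hoxb3 from 2797 ± 143 to 345 ± 10.5. Hoxb9 was at least 9.29-fold lower and Hoxc10 at least 4.16-fold lower. The 4 that rose were Hoxd13 (0.71), Hoxa11 (0.48), Meis1 (0.57) and Meis2 (0.90).

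Glycolysis genes changed by a mean of 0.22 in FIH null cells (adjusted p = 2.34e-05, 0.552 with an estimated correlation and 0.173 with fry), a mean that turned to -0.04 with scaling to hybridization controls. Of 19 glycolysis genes 3 rose and 0 fell over all genes, 6 and 0 adjusted over the list alone. The 3 were the aldolase gene Aldoc (0.87), the lactate exporter gene Slc16a3 (0.64, adjusted p = 0.0805 without a variance trend) and Pdk1 (0.39, adjusted p = 0.148 with scaling to hybridization controls). Pfkp changed by 0.26 without passing (adjusted p = 0.0755). Hypoxia-inducible genes went both ways: Ankrd37, Egln3 (0.81), the collagen hydroxylase genes P4ha1 (0.57) and P4ha2 (0.36), Car12 (0.58) and Ddit4 (0.33) rose. The feedback inhibitor gene Errfi1 (-0.75), Ndrg1 (-0.46), the vasodilator gene Adm (-0.83) and Ccng2 (-0.27) fell. Adjusted over the list alone 12 rose and 7 fell. Their mean of 0.10 (adjusted p = 0.0453; adjusted p = 0.841 with an estimated correlation) turned to -0.14 with scaling to hybridization controls. The call ended without wild type replicate 2 (adjusted p = 0.07), without FIH null replicate 2 (adjusted p = 0.12) and with median centring (0.0872). It also ended without a variance trend (0.0671), with the filter at the 75th percentile (0.154), with only the compared groups (0.0538) and with the largest pseudocount tried (0.0522).

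Of 14 contractile and myofibroblast genes 5 fell and 0 rose in FIH null cells, and 7 fell and 0 rose adjusted over the list alone (mean -0.22, adjusted p = 0.00708; adjusted p = 0.716 with an estimated correlation and 0.051 without FIH null replicate 2). The smooth muscle actin gene Actg2 fell from 1911 ± 78.4 to 606 ± 151 and the calponin gene Cnn1 from 3640.3 ± 137 to 2306 ± 209.5. Smtn (-0.39) also fell, with the growth factor gene Ccn2 (-0.39) and Acta2 (-0.27). The Ccn2 call ended without wild type replicate 2 (adjusted p = 0.0856) or FIH null replicate 2 (0.0773), and the Acta2 call without any one of the 4 arrays compared (adjusted p from 0.0866 to 0.165). Of 20 NRF2 targets, genes of the response to oxidants, 6 rose and 1 fell over all genes, and 7 and 1 adjusted over the list alone. The NRF2 mean was 0.15 (adjusted p = 0.00165; adjusted p = 0.205 with an estimated correlation). Scaling to hybridization controls turned it to -0.11 and ended the call (adjusted p = 0.0935). The quinone reductase gene Nqo1 rose from 3692 ± 54.9 to 5696 ± 2.12 and the glutathione transferase gene Gstm1 by 0.46, while Gsta4 fell (log2 change -0.57). The Gstm1 call ended without wild type replicate 2 (adjusted p = 0.0851) or FIH null replicate 1 (adjusted p = 0.132). Me1, a malic enzyme gene, rose by 0.23, which turned to -0.03 with scaling to hybridization controls. The Gsta4 and Me1 calls ended without any one of the 4 arrays (adjusted p from 0.0696 to 0.13 and from 0.0847 to 0.189).

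Further lists passed the list test in FIH null cells with few or no single genes changed. Oxidative phosphorylation genes had a mean of 0.08 (adjusted p = 1.52e-04; adjusted p = 0.552 with an estimated correlation and 0.303 with quantile normalization), with 0 of 59 changed over all genes and adjusted over the list alone. That mean turned to -0.18 with scaling to hybridization controls (adjusted p = 0.297). Ndufa2 (0.19, adjusted p = 0.0575) and Ndufs8 (0.25, adjusted p = 0.0582) were the nearest to passing. Cell cycle genes had a mean of 0.06 (adjusted p = 0.00495; adjusted p = 0.552 with an estimated correlation), which turned to -0.19 with scaling to hybridization controls (adjusted p = 0.453). Of 42 only 1 was higher over all genes and 0 adjusted over the list alone, and the list's call ended with other settings (adjusted p = 0.21 with quantile normalization and 0.0508 without FIH null replicate 1). That gene was the mitotic kinase gene Aurkb (0.23, turned to -0.03 with scaling to hybridization controls), whose call ended without any one of the 4 arrays compared (adjusted p from 0.122 to 0.219). The list of amino acid deprivation and ER stress genes passed at adjusted p = 0.0498 with a mean of 0.09 (adjusted p = 0.552 with an estimated correlation), which turned to -0.17 with scaling to hybridization controls (adjusted p = 0.563). Its call ended without any one of the 8 arrays (adjusted p from 0.0514 to 0.0908). In that list Chac1 (0.34) and Mthfd2 (0.27) rose and Nupr1 (-0.37) fell over all genes, and 4 rose and 1 fell adjusted over the list alone. Each of these 3 calls ended when 1 of several arrays was left out (adjusted p up to 0.142, 0.195 and 0.0825). Adipocyte markers had a mean of -0.50 with 0 of 7 genes changed over all genes or adjusted over the list alone (adjusted p = 0.0494; adjusted p = 0.552 with an estimated correlation). The adipocyte call ended without wild type replicate 1 (adjusted p = 0.164), FIH null replicate 2 (0.245), double null replicate 1 (0.0514) or double null replicate 2 (0.0528).

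Further large falls in FIH null cells were those of the antisense transcript Hoxb5os (3874 ± 92.8 to 40 ± 20.9, at least 13.3-fold lower), the complement regulator gene C4bp (at least 8.37-fold), the interferon-inducible gene Ifi202b (at least 4.64-fold) and Nts (at least 3.36-fold). Among the top rises was that of the carboxylesterase gene Ces5a, from 460.4 ± 404 to 2977 ± 28.6 (log2 change 2.97, adjusted p = 0.00228, and 0.064 without a variance trend). Its wild type arrays read 745.9 and 174.9, the latter below the cutoff, and without that array the log2 change was 1.97. 1810062G17Rik was at least 2.5-fold higher. Ntng1 (34.9 ± 20.4 to 329.8 ± 16.1), Nos1ap (50.0 ± 17.2 to 295 ± 7.78) and Mylk2 (38.0 ± 1.48 to 261 ± 173) passed with signals near or below the cutoff. The Ntng1 and Nos1ap calls ended without any one of the 4 arrays compared (adjusted p from 0.0627 to 0.182 and from 0.0585 to 0.134). The Mylk2 call ended without either wild type array (0.089 and 0.0975) or FIH null replicate 2 (0.253). Ntng1 turned to -0.61 without the filter, where another probe set stands for the gene. Without a variance trend the calls of Ntng1, Nos1ap, Mylk2, Ccn2, Acta2, Gstm1, Gsta4, Me1, Aurkb and Mthfd2 ended too (adjusted p from 0.0544 for Mylk2 to 0.12 for Mthfd2). Calls were also lost with scaling to hybridization controls for Gstm1 (0.118), Mthfd2 (0.88) and Chac1 (0.496), with the mean of probe sets for Aurkb (0.0762) and Mthfd2 (0.0771), and with only the compared groups for Mylk2 (0.103). The Acta2 call ended with median centring (0.0817) and with centring per chromosome (0.0567), and leaving out either VHL null array ended those of Ntng1 (0.059 and 0.0589) and Mylk2 (0.0526 and 0.0528). With the largest pseudocount Mylk2 had adjusted p = 0.0674.

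In all, 758 genes changed between FIH null and wild type cells (6.55% of those tested), 227 higher and 531 lower, and 212 of them at least 2-fold, 17 higher and 195 lower. The count was 382 without wild type replicate 1, 379 without wild type replicate 2, 353 without FIH null replicate 1 and 391 without FIH null replicate 2, and the larger share of falls turned with median centring, where 1426 genes passed and 71.2% of them were higher. Scaled to hybridization controls 5126 passed, 1.37% of them higher.

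Double null cells were compared with VHL null cells to ask what loss of FIH adds where VHL is already lost. A set of hypoxia-inducible genes that were already high or still low in VHL null cells was higher again in double null cells. Car9, a carbonic anhydrase gene, rose from 339 ± 137 to 8026 ± 365 (adjusted p = 2.89e-07), where 1 of the VHL null arrays, at 242.6, was below the cutoff. Adm rose from 4579 ± 327 to 17582 ± 1774 and Egln3 from 4300.1 ± 158 to 17118 ± 588. Pdk1 read 32524 ± 85.1 and 35074 ± 247.

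Of 34 hypoxia-inducible genes, 21 were higher and 4 lower in double null than in VHL null cells, over all genes and adjusted over the list alone (mean 0.54, adjusted p = 9.68e-05; adjusted p = 0.755 with an estimated correlation). Besides Car9, the highest ranking were Ankrd37 (2.17), Egln3 (1.99) and Adm (1.94). The 4 that fell were Errfi1 (-0.82), the lipase inhibitor gene Angptl4 (-0.90), the growth factor gene Pdgfb (below the cutoff in double null cells) and Vldlr (-0.35). Glycolysis genes did not pass as a list (mean 0.21, adjusted p = 0.176). Of 19 there were 8 higher and 1, Pfkm (-0.24), lower over all genes, and 9 and 1 adjusted over the list alone. Without double null replicate 2 the glycolysis list passed (mean 0.34, adjusted p = 6.83e-04), and without double null replicate 1 its mean was 0.07. Aldoc rose by 0.74, the regulatory kinase gene Pfkfb3 by 0.89, Slc2a1 by 0.32 and Hk2 by 0.26. The Slc2a1 and Hk2 calls ended with scaling to hybridization controls (adjusted p = 0.0589 and 0.278) and with centring per chromosome (0.0506 and 0.156). That of Hk2 ended also without VHL null replicate 2 (adjusted p = 0.0714) or double null replicate 1 (0.0814).

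Lipid synthesis genes were lower again in double null cells. Of 28 there were 16 that fell and 1, Ebp (0.18), that rose, over all genes and adjusted over the list alone (mean -0.21, adjusted p = 5.57e-05; adjusted p = 0.149 with an estimated correlation). The sterol demethylase gene Cyp51 fell from 8279.8 ± 514 to 5065 ± 141, and Srebf2, which encodes the regulator of cholesterol synthesis, from 4422 ± 84.0 to 2995 ± 267. Fads2 (-0.49) and Fads1 (-0.45) fell as well, the Fads1 call ending with the mean of its probe sets (-0.05, adjusted p = 0.722). Of 24 interferon-stimulated genes 13 rose and 2, Ifit3 (-0.68) and Irf1 (-0.29), fell, over all genes and adjusted over the list alone (mean 0.72, adjusted p = 0.01; adjusted p = 0.277 with an estimated correlation). Rtp4 rose from 313 ± 29.9 to 1207 ± 18.2, near its wild type signal of 1216 ± 65.4. The viral RNA sensor gene Ifih1 rose by 1.17, Igtp by 1.26 and Ifi35 by 0.69.

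Of 21 p53 targets, 13 rose and 2, Perp (-0.46) and Plk2 (-0.21), fell, over all genes and adjusted over the list alone (mean 0.48, adjusted p = 3.93e-04; adjusted p = 0.492 with an estimated correlation). Cdkn1a, which encodes an inhibitor of cyclin-dependent kinases, rose from 8962 ± 312 to 23752 ± 2360.5, Trp53inp1 from 3318 ± 294 to 10281 ± 594, Ccng1 from 26187 ± 177 to 50658 ± 1353 and Zmat3 by 0.94 on the log2 scale. Among 31 genes of the Hox list, 13 were higher and 17 lower in double null cells, over all genes and adjusted over the list alone (mean -1.07, adjusted p = 0.0257; adjusted p = 0.277 with an estimated correlation). The list's call ended without VHL null replicate 1 (adjusted p = 0.0752) or 2 (0.0858), without the filter (0.0546), with the filter at the 75th percentile (0.0958), without a variance trend (0.0712), with centring per chromosome (0.0637) and with scaling to hybridization controls (0.313). Hoxd13 was at least 44.6-fold higher, Hoxb6 at least 26.0-fold lower, Hoxb2 at least 12.6-fold lower, and Hoxa5 fell by 2.72 on the log2 scale.

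Besides Hoxd13, the top rises included that of Pycard, which encodes an inflammasome adaptor, from 33.5 ± 36.4 to 4477 ± 448, at least 15.4-fold. The cartilage collagen gene Col10a1 was at least 14.7-fold higher, the hindlimb gene Tbx4 at least 7.58-fold, the limb and heart gene Hand2 at least 5.10-fold and Armh4 at least 4.45-fold. Besides Zic1, at least 49.2-fold lower, the top falls were of the Hox clusters and their neighbours: Hoxc8 (at least 60.5-fold), Hoxc4 (at least 35.5-fold), Hoxc5 (at least 25.8-fold) and Hoxb5os (at least 18.1-fold). Gm6958 was at least 29.4-fold lower. Hif1an fell by 0.66 (adjusted p = 0.00131). Vhl was higher by 0.41 (adjusted p = 0.0142), a call that ended without VHL null replicate 1 (adjusted p = 0.0743), without double null replicate 1 (0.0831), with only the compared groups (0.098), with centring per chromosome (0.0752) and with scaling to hybridization controls (0.0802).

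In all, 4355 genes changed between double null and VHL null cells (37.7% of those tested), 2574 higher and 1781 lower, and 693 of them at least 2-fold, 419 higher and 274 lower. The larger share of rises turned with scaling to hybridization controls (31.7% of calls higher).

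Double null cells were compared with wild type cells. Most hypoxia genes, glycolysis genes and p53 targets were higher and most lipid synthesis genes lower in double null cells. Of these lists only lipid synthesis passed with an estimated correlation. All of them passed with fry, which does not compare a list with other genes (largest fry adjusted p = 0.00101). Tmem45a rose from 934 ± 164 to 33187 ± 5457 (log2 change 5.13, adjusted p = 4.11e-10) and Egln3 from 618 ± 21.6 to 17118 ± 588 (log2 change 4.76, adjusted p = 6.57e-11). Fads1, a desaturase gene, fell from 17449 ± 233 to 6193 ± 13.9.

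Of 34 hypoxia-inducible genes, 30 rose and 1, Pdgfb (below the cutoff in double null cells), fell over all genes, and 31 rose and 1 fell adjusted over the list alone (mean 1.83, adjusted p = 1.79e-25; adjusted p = 0.373 with an estimated correlation). Adm rose by 4.13 and Bnip3 by 2.90. Glycolysis genes had 16 of 19 higher and 2, Eno2 (-1.14) and Pfkm (-0.30), lower over all genes, and 16 and 3 adjusted over the list alone (mean 1.27, adjusted p = 1.20e-11; adjusted p = 0.434 with an estimated correlation). Aldoc rose by 2.98, Pdk1 by 2.76, Pfkp by 2.46 and Slc2a1 by 2.19. Of 28 lipid synthesis genes 27 fell over all genes and 28 adjusted over the list alone (mean -1.03, adjusted p = 5.95e-20, and adjusted p = 0.0111 with an estimated correlation). Fads2 was at -1.71, Fads1 at -1.49, Fdps at -1.48 and Cyp51 at -1.43.

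The p53 targets had 13 of 21 higher and 2, Perp (-1.69) and Sesn1 (-0.28), lower, over all genes and adjusted over the list alone. Their mean of 0.49 (adjusted p = 2.09e-05; adjusted p = 0.434 with an estimated correlation) turned to -0.03 with scaling to hybridization controls. Cdkn1a rose by 2.06, Trp53inp1 by 1.67 and Ccng1 by 1.01. Of 14 contractile genes 7 rose and 2, Actg2 (-2.07) and Smtn (-0.32), fell, over all genes and adjusted over the list alone. The contractile mean of 0.25 (adjusted p = 0.0274; adjusted p = 0.592 with an estimated correlation) turned to -0.27 with scaling to hybridization controls. Cnn1 rose by 1.44, Ccn2 by 1.31 and Ccn1 by 0.80. The contractile call ended without wild type replicate 2 (adjusted p = 0.0649), without double null replicate 1 (mean 0.10, adjusted p = 0.0834), with quantile normalization (0.108), without a variance trend (0.0835) and with centring per chromosome (0.109).

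Tmem45a and Egln3 rose most among genes above the cutoff on all 4 arrays. Top rises from wild type signals below the cutoff were of 2610528A11Rik (at least 40.3-fold), Car9 (at least 27.6-fold), Pycard (at least 15.4-fold, adjusted p = 0.202 with a pseudocount of 1), Tbx4 (at least 7.58-fold) and Ppp1r3b (at least 5.67-fold). Top falls, to double null signals below the cutoff, were of Hoxc8, from 12838 ± 1814 to 124 ± 101, at least 44.1-fold, Gm6958 (at least 21.5-fold), Zic1 (at least 20.3-fold), Hoxc4 (at least 19.5-fold), Hoxb5os (at least 13.3-fold) and C4bp (at least 8.37-fold). Between double null and wild type cells 4789 genes changed (41.4% of those tested), 2060 higher and 2729 lower, and 805 of them at least 2-fold, 425 higher and 380 lower. With median centring 55.3% of the genes that passed were higher rather than 43.0%, and with scaling to hybridization controls 9165 genes passed, 5.56% of them higher. With centring per chromosome, which by construction brings each chromosome's median change near 0, 51.9% were higher.

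Double null cells were compared with FIH null cells to ask what loss of VHL does where FIH is already lost. Most hypoxia and glycolysis genes rose here as well, and most lipid synthesis genes fell. Of these lists only lipid synthesis passed with an estimated correlation. All of them passed with fry, which does not compare a list with other genes (largest fry adjusted p = 5.96e-04). Adm rose from 549.8 ± 40.2 to 17582 ± 1774 (log2 change 4.96, adjusted p = 1.42e-10), Hk2 from 3906 ± 180.0 to 16924 ± 1255 and Ndufa4l2, a mitochondrial protein gene, from 81.3 ± 9.90 to 4852 ± 197, at least 16.7-fold. Fdps fell from 43422 ± 1837 to 14619.9 ± 536 (log2 change -1.57, adjusted p = 1.29e-08).

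Hypoxia-inducible genes had 31 of 34 higher and 1, Pdgfb (below the cutoff in double null cells), lower, over all genes and adjusted over the list alone (mean 1.73, adjusted p = 4.78e-22; adjusted p = 0.466 with an estimated correlation). Egln3 was at 3.95, Tmem45a at 4.66 and Bnip3 at 2.90. Glycolysis genes had 16 of 19 higher and 3, Eno2 (-1.26), Pfkm (-0.41) and Pfkfb4 (-0.49), lower, over all genes and adjusted over the list alone (mean 1.04, adjusted p = 1.77e-08; adjusted p = 0.483 with an estimated correlation). Pdk1 rose by 2.36, Pfkp by 2.19, Hk2 by 2.11 and Slc2a1 by 2.02. Of 28 lipid synthesis genes 27 fell over all genes and 28 adjusted over the list alone (mean -1.0, adjusted p = 1.51e-18, and adjusted p = 0.0128 with an estimated correlation). Fads2 was at -1.64, the stearoyl desaturase gene Scd1 at -1.33 and Fads1 at -1.32.

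Contractile genes had 9 of 14 higher and 0 lower, over all genes and adjusted over the list alone (mean 0.47, adjusted p = 0.00104; adjusted p = 0.606 with an estimated correlation). Cnn1 rose by 2.10, Ccn2 by 1.70, the myosin light chain gene Myl9 by 0.94 and Ccn1 by 0.82. The p53 targets had 14 of 21 higher and 2, Perp (-2.08) and Sesn1 (-0.51), lower over all genes, and 15 and 4 adjusted over the list alone (mean 0.52, adjusted p = 1.07e-04; adjusted p = 0.483 with an estimated correlation). Trp53inp1 rose by 2.26, Cdkn1a by 2.11 and Ccng1 by 1.10.

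Against FIH null cells the top rises, from signals below the cutoff, were of Ifi202b (36.2 ± 29.0 to 22462 ± 76.6, at least 77.2-fold), 2610528A11Rik (at least 40.3-fold), Stc1 (at least 18.1-fold), Pycard (at least 15.4-fold, adjusted p = 0.065 with a pseudocount of 1) and Ppp1r3b (at least 5.67-fold). Falls to signals below the cutoff, in an order that the bounds leave open, were of Hoxc8 (at least 36.6-fold), Pcdh17 (at least 22.8-fold), Alx1 (at least 12.9-fold), Zfp945 (at least 4.45-fold), the transcription factor genes Tfap2b (at least 1.95-fold) and Sox2 (at least 1.88-fold). Vhl fell by 1.82 (adjusted p = 3.17e-07). Hif1an fell by 0.40 (adjusted p = 0.0176), a call that ended with the mean of its probe sets (adjusted p = 0.959) and without FIH null replicate 1 (0.0633), FIH null replicate 2 (0.0794) or double null replicate 2 (0.119). In all, 5267 genes changed between double null and FIH null cells (45.5% of those tested), 2380 higher and 2887 lower, and 901 of them at least 2-fold, 575 higher and 326 lower. Higher were 45.2% as reported, 16.1% of the 6875 that passed with scaling to hybridization controls, and 51.0% with centring per chromosome. That centring by construction brings each chromosome's median change near 0.

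The comparisons of VHL loss with and without FIH share no array, and their overlap shows which genes differed between the VHL genotypes in both backgrounds. Line of origin coincides with genotype, so the overlap cannot tell loss of VHL from differences between the lines. In both backgrounds, 991 genes rose where 368 would be expected of independent lists, and 1709 fell where 819 would be expected. The comparisons share the estimate of each gene's spread, so they are not fully independent and the expected numbers may be too low. The shared split was 311 higher and 5060 lower with scaling to hybridization controls (5.79% higher against 36.7% as reported). With centring per chromosome, which by construction brings each chromosome's median change near 0, 52.2% were higher. Of the 241 shared changes of at least 2-fold, 151 were rises and 90 falls (62.7% higher). Of the genes that passed in both, 2700 moved the same way and 387 the opposite way (87.5% the same), and across genes, which are not independent replicates, the changes correlated with r = 0.438. The top shared rises by mean log2 difference, all with a group below the cutoff, were of Ifi202b, Stc1, Ppp1r3b, 2610528A11Rik, Tafa2 and Kbtbd11, the last from 136 ± 119 in wild type and 52.5 ± 37.5 in FIH null to 2238 ± 35.6 in VHL null and 1649.7 ± 349 in double null cells. Top shared falls, all but Postn with groups below the cutoff and in an order that is open, were of Pcdh17, Alx1, Sox2, Slc4a10, Tfap2b and the matrix gene Postn, which read 4884 ± 136, 12489.6 ± 275, 795 ± 26.4 and 2128 ± 299 in the same order.

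FIH loss in both VHL backgrounds gave 123 shared rises where 50.5 would be expected and 229 shared falls where 81.8 would be expected. These expected numbers have the same limit of a shared estimate of spread. Of the genes that passed in both, 352 moved the same way and 132 the opposite way (72.7% the same), and the changes correlated across genes with r = 0.246. Top shared rises were those of Hoxd13, the forebrain and limb gene Lhx2 (219.9 ± 42.9 to 498 ± 134 and 249.6 ± 31.3 to 3427 ± 911), the matrix gene Aspn, the microtubule gene Map2, the caveola gene Cavin2 and Ankrd37. The top shared falls were of Hoxb5os, Zic1, Hoxc4, C4bp, Hoxc5 and Hoxb6, all with a group below the cutoff. The count of 352 was 213 without wild type replicate 1, 194 without wild type replicate 2, 187 without FIH null replicate 1 and 196 without FIH null replicate 2, and with median centring 547 genes moved the same way, 65.3% of them higher rather than 34.9%. Scaling to hybridization controls gave 33 shared rises and 1905 shared falls.

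**Figure D2:**
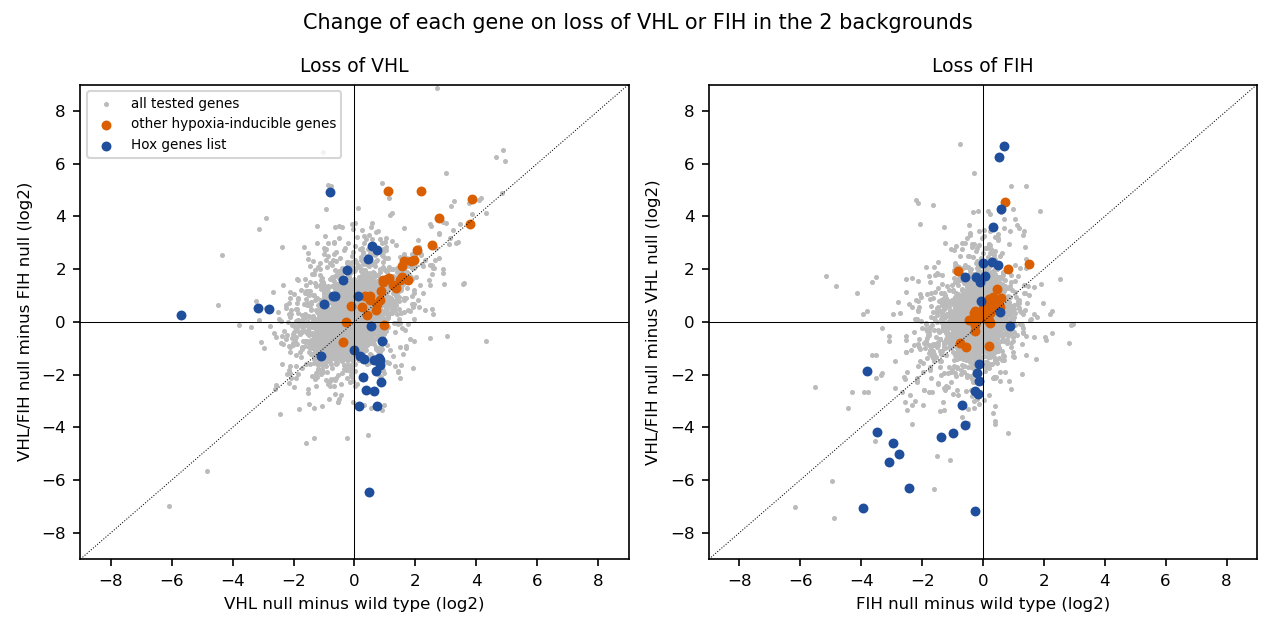
Each point is a tested gene (hypoxia-inducible genes orange, Hox list blue), with its log2 change for VHL loss in cells with (x) and without FIH (y) on the left, and for FIH loss in cells with (x) and without VHL (y) on the right. Across genes r is 0.438 on the left and 0.246 on the right, and most hypoxia-inducible genes lie above 0 on both axes on the left.

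The interaction asks whether the change with FIH loss differed between cells with and without VHL. It was positive for 16 of 34 hypoxia-inducible genes, whose list did not pass with an estimated correlation (adjusted p = 0.614). Adm changed by -0.83 with FIH loss in cells with VHL and by 1.94 in cells without, an interaction of 2.77 (adjusted p = 6.99e-07). Egln3 had an interaction of 1.18 and Ndrg1 of 0.53. Car9 had a positive one too (adjusted p = 4.48e-05), a value that is not a measure of size because its signals of 144 ± 19.2 in wild type and 245 ± 7.50 in FIH null cells were below the cutoff.

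Of 34 hypoxia-inducible genes 16 had a positive and 1, Angptl4 (-1.11), a negative interaction over all genes, and 18 and 1 adjusted over the list alone (mean 0.44, adjusted p = 0.00136; adjusted p = 0.614 with an estimated correlation). The p53 targets had 12 of 21 positive and 2, Perp (-0.84) and Plk2 (-0.32), negative, over all genes and adjusted over the list alone (mean 0.51, adjusted p = 6.09e-04; adjusted p = 0.408 with an estimated correlation). Trp53inp1 was at 2.22, Cdkn1a at 1.46, Ccng1 at 1.04 and Ei24 at 0.79. Interferon-stimulated genes had 7 of 24 positive and 0 negative, over all genes and adjusted over the list alone (mean 0.64, adjusted p = 0.0165; adjusted p = 0.408 with an estimated correlation, 0.0557 without the filter and 0.065 with scaling to hybridization controls). Rtp4 (1.64), Xaf1 (below the cutoff in VHL null cells), Ifih1 (1.04) and Ifi35 (0.53) were among them, the Ifi35 call ending with the mean of its probe sets (adjusted p = 0.057) and without probe sets that may cross-hybridize (0.106). Contractile genes had 6 of 14 positive and 1, Mylk (-1.03), negative over all genes, and 8 and 1 adjusted over the list alone (mean 0.33, adjusted p = 0.0071; adjusted p = 0.523 with an estimated correlation; mean 0.18 without double null replicate 1). Among them Cnn1 had 1.62, the smooth muscle actin gene Acta2 1.33, Myl9 1.26 and Ccn2 0.51.

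Lipid synthesis genes had a negative interaction for 10 of 28 and a positive one for 0 over all genes, and for 12 and 1 adjusted over the list alone (mean -0.19, adjusted p = 4.97e-04; adjusted p = 0.215 with an estimated correlation). Srebf2 (-0.54) and Scd1 (-0.43) were examples. So were Sc5d (-0.58), of whose 3 probe sets 1 passed the opposite way, and Cyp51 (-0.48), and with the mean of probe sets their adjusted p was 0.753 and 0.339. Oxidative phosphorylation genes had 7 of 59 negative and 0 positive over all genes, and 6 and 0 adjusted over the list alone. Their mean of -0.11 (adjusted p = 6.53e-04; adjusted p = 0.408 with an estimated correlation and 0.363 with quantile normalization) turned to 0.00277 with scaling to hybridization controls. Ndufs8 had -0.78, and the calls of Ndufa2 (-0.40) and the ATP synthase gene Atp5a1 (-0.41) ended with centring per chromosome (adjusted p = 0.638 and 0.546). That of Ndufa4 (-0.32) ended with scaling to hybridization controls (0.104) and without wild type replicate 2 (0.0666), FIH null replicate 1 (0.0807) or VHL null replicate 1 (0.0668). Glycolysis genes did not pass as a list (mean -0.02, adjusted p = 0.319; -0.15 and adjusted p = 0.0143 without double null replicate 1). There were 3 positive members, Pfkfb3 (0.66), Slc2a3 (1.07) and Hk2 (0.32), and 2 negative, Pdk1 (-0.28) and Pfkm (-0.35). Of these the calls of Pfkfb3, Slc2a3, Hk2 and Pdk1 each ended when 1 of several arrays was left out, with adjusted p up to 0.0635 (without VHL null replicate 2), 0.0858 (without VHL null replicate 1), 0.14 (without FIH null replicate 1) and 0.14 (without FIH null replicate 2). These 4 calls and that of Ndufa4 also ended without a variance trend (adjusted p from 0.0532 for Pfkfb3 to 0.0973 for Hk2). The mean of probe sets ended those of Slc2a3 (0.128) and Pdk1 (0.0553), and leaving the filter off those of Pdk1 (0.0516) and Hk2 (0.0535). Scaling to hybridization controls ended that of Pdk1 (0.26), median centring that of Hk2 (0.166), and centring per chromosome those of Hk2 (0.162) and Cyp51 (0.0539).

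The top positive interactions were of Pycard (7.48, adjusted p = 0.0634 with a pseudocount of 1), Nts (6.89), the glutamate transporter gene Slc1a6 (6.84), the receptor gene Ror1 (6.65, adjusted p = 0.85 without the filter), Ifi202b (6.17) and Shox2 (6.05). Shox2, a limb gene, read 858 ± 55.9 in wild type, 273 ± 93.2 in FIH null, 462 ± 13.5 in VHL null and 10229 ± 28.3 in double null cells. The top negative ones were of Hoxc8 (-6.93), Nmu (-5.02), Gm6958 (-4.72), the lipid receptor gene Lpar3 (-4.25), Zfp945 (-4.16) and the collagen repeat gene Cthrc1 (-4.15). Cthrc1 read 6084 ± 185, 2832 ± 3.46, 11978 ± 161 and 316 ± 144 in the same order. Each of these has at least 1 array below the cutoff, so neither the value nor the order of their interactions is a measure of size. An interaction passed for 2533 genes (21.9% of those tested), 1554 positive and 979 negative, and 636 of them reached at least 2-fold, 486 positive and 150 negative. Without FIH null replicate 1 the count was 1646, and with median centring 40.4% of the interactions were positive rather than 61.4%.

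**Figure D3:**
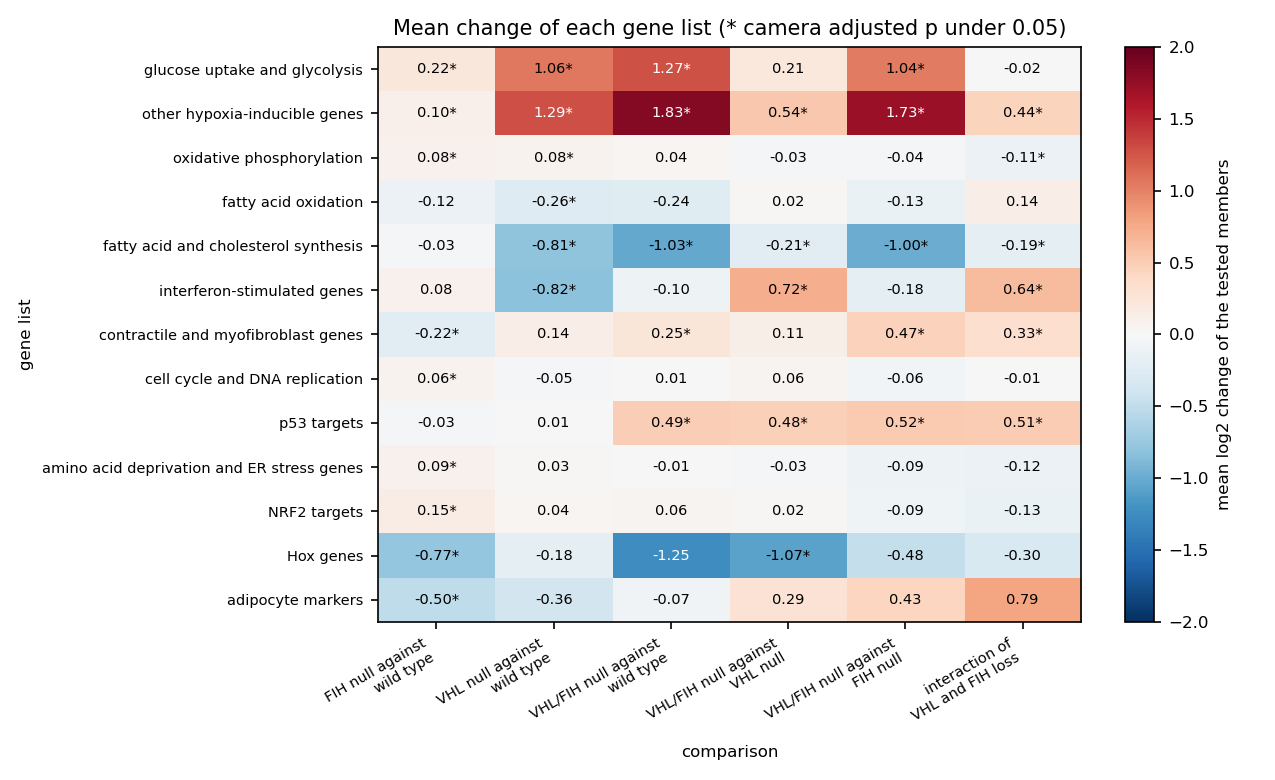
Mean log2 change of the tested members of each gene list (rows of the heat map) in the 6 comparisons (columns), with a star where the list passed at camera adjusted p below 0.05. Hypoxia-inducible genes had their highest mean and lipid synthesis genes their lowest in double null cells against wild type, and of the lists that passed the means turned sign with scaling to hybridization controls for glycolysis, hypoxia, oxidative phosphorylation, cell cycle, amino acid deprivation and NRF2 lists in FIH null cells, for oxidative phosphorylation in VHL null cells (with quantile normalization too) and in the interaction, and for p53 and contractile lists in double null cells against wild type.

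Genes that mark where in the body a fibroblast came from differed between the groups. Hoxc8 read 12838 ± 1814 in wild type, 10657 ± 714 in FIH null, 17622 ± 115 in VHL null and 124 ± 101 in double null cells, and Hoxd13 read 6615 ± 557, 10776 ± 288, 111 ± 11.6 and 12970.5 ± 35.4. Tbx4 read 36.8 ± 18.2, 58.1 ± 11.8, 14.3 ± 9.97 and 2207 ± 86.8. An interaction passed for 27 of the 31 genes of the Hox list (87.1%), against 21.9% of all tested genes.

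**Figure D4:**
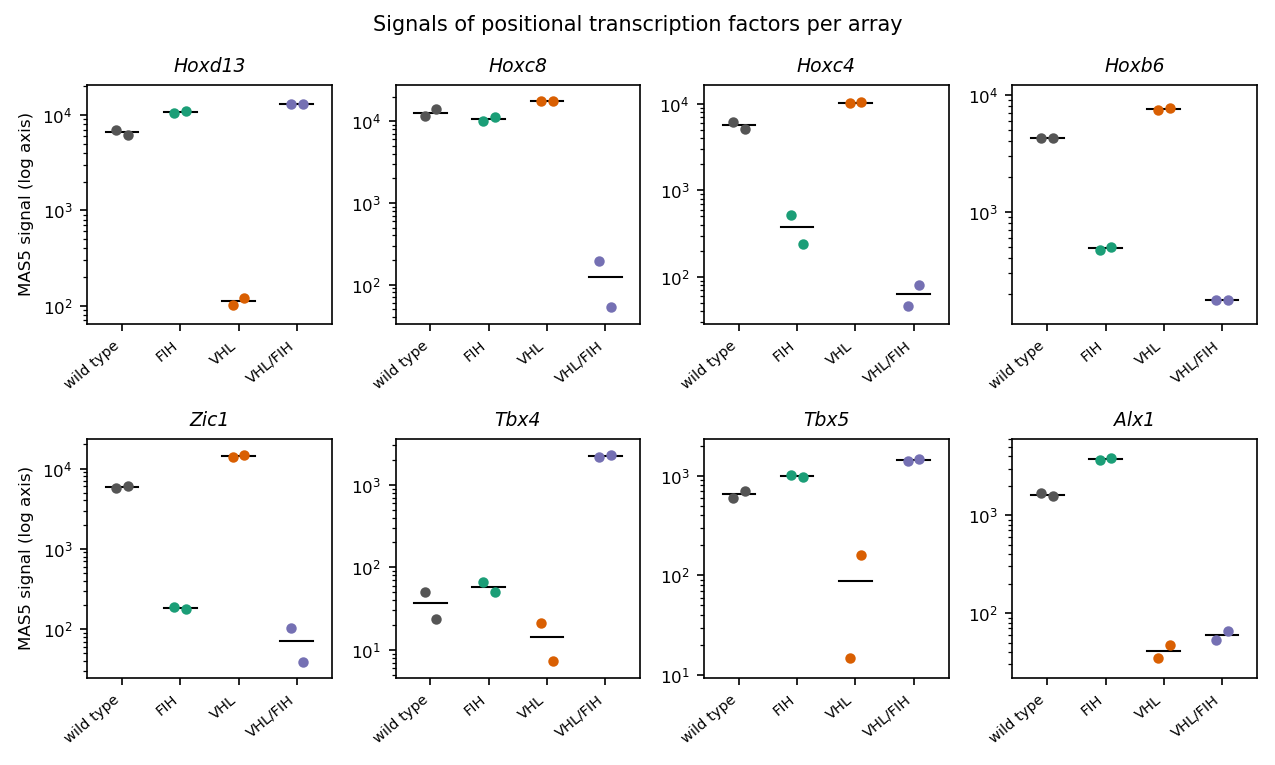
MAS5 signal of each array (points, log axis, intensity units) and group mean (dash) for 8 genes of body position in the 4 groups. Hoxd13 was low in VHL null cells, Hoxc8 was low in double null cells, and Hoxb6 and Zic1 were low in FIH null and double null cells.

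By the probe set that represents each, the Y-linked genes Eif2s3y, Kdm5d and Uty were above the cutoff on every array. Another tested probe set of Kdm5d read 172 ± 4.03 in VHL null cells, below the cutoff, and 438 ± 75.5 in wild type cells. Eif2s3y read 5737 ± 347 in wild type, 8498 ± 228 in FIH null, 3592 ± 143 in VHL null and 8766 ± 903 in double null cells. Its fall in VHL null cells (log2 change -0.67, adjusted p = 9.04e-05) went with that of Kdm5d, a histone demethylase gene (log2 change -1.31, adjusted p = 1.04e-04). Both were higher in double null than in VHL null cells, Eif2s3y by 1.28 and Kdm5d by 1.70, as was Uty by 0.78. Eif2s3y was also higher in FIH null than in wild type cells (0.57, adjusted p = 0.00165) and in double null than in wild type cells (0.61), as was Uty in double null cells (0.56). Another tested probe set of Uty changed less in double null cells, by 0.11 (SE 0.14) against wild type and by 0.36 (SE 0.14) against VHL null cells. The calls in double null cells against wild type ended with scaling to hybridization controls (adjusted p = 0.426 and 0.797).

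Markers of other cell types did not pass as lists in any comparison, apart from the adipocyte markers in FIH null cells. The smallest adjusted p over the 6 comparisons was 0.655 for endothelial markers, 0.756 for epithelial markers, 0.655 for neural and neural crest markers, 0.211 for skeletal muscle markers and 0.135 for cartilage and bone markers. Of 18 macrophage markers 4 were tested, too few for a list test, and the scavenger receptor gene Cd68 read 446 ± 50.8, 395 ± 72.3, 516 ± 0.212 and 664 ± 125 in wild type, FIH null, VHL null and double null cells. Among the other lists, none of the 6 comparisons passed for HIF pathway components (smallest adjusted p 0.40), the tricarboxylic acid cycle (0.0975), the Notch pathway (0.0975), NF-kB targets and inhibitors (0.133), extracellular matrix (0.176), matrix remodelling enzymes (0.40) or imprinted genes (0.101). Mean, median and test had the same sign in all 36 list results that passed, and differed in sign in 36 of the 114 that did not.

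Medians of all genes of a chromosome differed between groups. Against wild type, chromosome 18 had a median of 0.11 in FIH null, 0.10 in VHL null and -0.18 in double null cells, and chromosome 9 a median of -0.09, -0.01 and 0.18. In each of the 6 comparisons the spread of the chromosome medians of 11538 placed genes exceeded that of 2000 shuffles of the genes (permutation p = 0.0005, raw and adjusted, the smallest that number of shuffles can give). Between double null and VHL null cells the median change was 0.21 on chromosome 16 and -0.24 on chromosome 18.

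**Figure D5:**
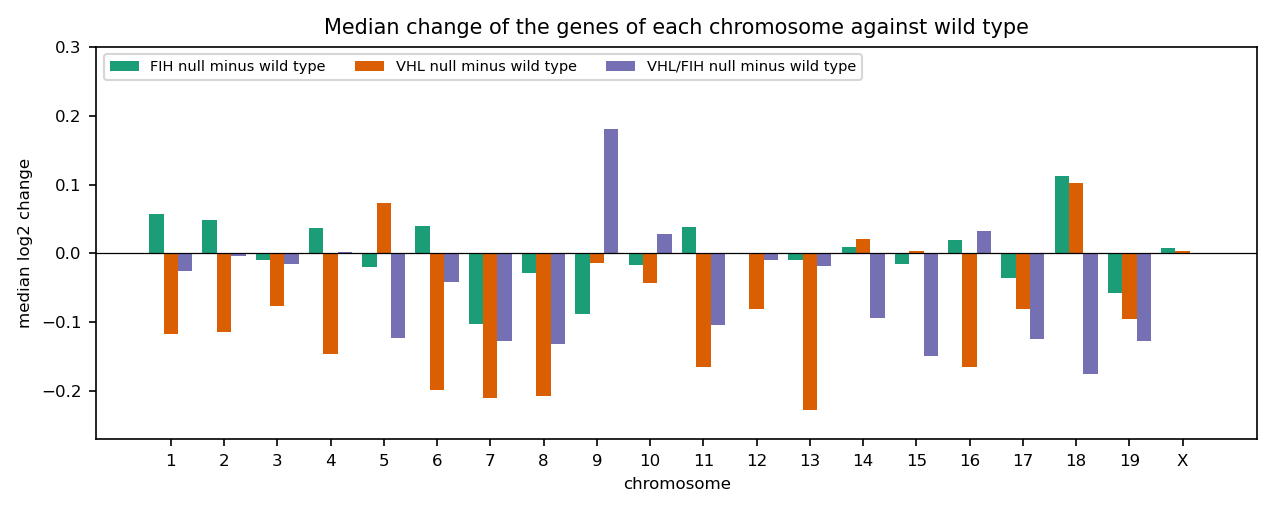
Bars are the median log2 change of the tested genes of each mouse chromosome (x) in FIH null, VHL null and double null cells against wild type (y, log2). Chromosome 18 was at 0.11, 0.10 and -0.18 and chromosome 9 at -0.09, -0.01 and 0.18.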

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

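The tests of Hox genes against loss of VHL, loss of FIH and sex, and the test of remaining Vhl transcript, were chosen after the result was seen. Each result here stands out because the change with FIH loss differed between cells with and without VHL, by a test of that difference (the interaction). It passed for 2533 genes and for 6 lists, whose mean interactions were 0.44 for other hypoxia-inducible genes, -0.11 for oxidative phosphorylation, -0.19 for fatty acid and cholesterol synthesis, 0.64 for interferon-stimulated genes, 0.33 for contractile genes and 0.51 for p53 targets. None of these 6 lists passed with an estimated correlation (adjusted p from 0.215 to 0.614). The top positive single-gene interactions were Pycard 7.48, Nts 6.89, Slc1a6 6.84, Ror1 6.65, Ifi202b 6.17 and Shox2 6.05, and the top negative ones Hoxc8 -6.93, Nmu -5.02, Gm6958 -4.72, Lpar3 -4.25, Zfp945 -4.16 and Cthrc1 -4.15. Each of these, and Car9 below, has at least 1 array under the signal cutoff of 291.1, so that their values and order are not a measure of size. Among hypoxia genes the values were Adm 2.77, Car9 3.84, Egln3 1.18 and Ndrg1 0.53, and among glycolysis genes Pfkfb3 0.66, Slc2a3 1.07, Pdk1 -0.28 and Hk2 0.32.

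Hypoxia-inducible genes were higher in double null than in VHL null cells, with a mean log2 change of 0.54 (adjusted p = 9.68e-05; adjusted p = 0.755 with an estimated correlation, where the list no longer passed). Less remaining Vhl signal in the double null cells is argued against, because Vhl was higher there by 0.41 (from 0.27 to 0.53 over the alternatives, 5 of which ended its call), but the deleted exons are unknown, so less intact transcript stays open. A shift of all genes of that signal level is argued against as well, because the list's mean stood at percentile 100 of 10000 random lists, which mostly ran from -0.13 to 0.21. Across the 34 members the changes with FIH loss in cells with and without VHL correlated with r = 0.54 (permutation p = 0.0026). The rank correlation was rho = 0.54 (permutation p = 0.0014), and r was 0.66 without Ankrd37 and Adm. This was 1 relation tested across genes that are not independent replicates, and over all tested genes r was 0.246. Of the members that passed in both comparisons of FIH loss, 7 moved the same way and 2 the opposite way (77.8%, exact interval 39.99 to 97.2%). Among all genes that passed in both, 72.7% moved the same way, so direction does not set the list apart. As a hypothesis loss of FIH itself may account for part of the pattern. The cell line that each group came from coincides with its genotype, so a difference between lines stays open and was not tested.

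Genes of the Hox list differed between the groups, with interactions for 27 of 31. Of the 13 that passed in both comparisons of VHL loss, 3 moved the same way and 10 the opposite way (23.1% the same, exact interval 5.04 to 53.8%, too narrow where genes of a cluster move together), which largely restates the interaction and leaves loss of VHL open. A wholly female group is argued against, as Y-linked Eif2s3y read at least 3490.3 on every array. Eif2s3y and Kdm5d fell in VHL null cells, so mixed sexes or partial Y loss stay open. Of the 13 that passed in both comparisons of FIH loss, 12 moved the same way and 1 the opposite way (92.3%, exact interval 64 to 99.8%, with the same limit), which could come from loss of FIH. Neither loss can be told from a different body position of the cells behind each floxed line, since each genotype has its own line.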

How the results depend on the processing

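Scaling to hybridization controls, centring per chromosome and the largest pseudocount were chosen after seeing the data, and all others were planned. With groups of 2 arrays, leaving one out leaves a lone array that is assumed to vary like the other groups, and signals near the cutoff limit what can be said of dim genes. Of 939 evaluations of 38 list results, 831 kept direction and side of the threshold, 102 no longer passed, 2 newly passed and 4 reversed, where direction is that of the list test, which sets a list against all other genes. Of 5661 evaluations of 251 results for named genes 5460 kept both, 140 no longer passed, 57 newly passed and 4 reversed. In FIH null cells the oxidative phosphorylation genes Ndufa2, Ndufs8, Ndufb2 and Atp5a1 newly passed with array weights and with the replicate block. So did the cell cycle genes Ccnb2 and Mcm6, and Pfkp and Trib3 (limma adjusted p from 0.0263 to 0.04996 with array weights and from 0.0285 to 0.046 with the block). Where no construction explains a change given here, the cause was not tested.

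Counts of changed genes that moved by more than 1.5 times were these. Median centring gave 1426 genes for FIH null against wild type (71.2% higher, 29.9% in the reported fit) and 547 for FIH loss in both backgrounds (65.3% higher, 34.9% as reported). By construction it raised FIH null against wild type, since the median signals were 285.4 and 283.8 in FIH null and 301.9 and 307.1 in wild type arrays. It turned the larger share in double null against wild type (55.3% higher, 43.0% as reported) and in the interaction (40.4% positive, 61.4% as reported). Without a variance trend the FIH counts were 421 and 213. Scaling to hybridization controls, which by construction lowers all null groups, gave 5126 genes for FIH null, 8406 for VHL null and 9165 for double null against wild type (1.37%, 5.16% and 5.56% higher). It also gave 5371 and 1938 for VHL and FIH loss in both backgrounds (5.79% and 1.70% higher), turned the larger share for double null against VHL null (31.7% higher), and gave 5, 11 and 10 lists for FIH null and double null against wild type and double null against FIH null. A change of at least 2-fold, a stricter rule, left 212, 627, 805, 693, 901 and 636 genes in the order FIH null, VHL null and double null against wild type, double null against VHL null, double null against FIH null and interaction, and 241 and 77 for VHL and FIH loss in both backgrounds. It turned the larger share for double null against wild type (52.8% higher), for double null against FIH null (63.8% higher) and for VHL loss in both backgrounds (62.7% higher, 36.7% as reported). Centring per chromosome turned the larger share for VHL null against wild type (51.7% higher) and for double null against wild type (51.9% higher). It also turned that for double null against FIH null (51.0% higher) and for VHL loss in both backgrounds (52.2% higher). By construction this centring removes each chromosome's median change and pulls such shares towards balance, so these turns do not test the reported shares. Under it 67.4 to 85.8% of the reported calls remained.

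For lists, quantile normalization gave 5 for FIH null against wild type. In the same order of comparisons, an estimated correlation gave 0, 1, 1, 0, 1 and 0 lists and fry, which does not compare a list with other genes, gave 3, 13, 15, 15, 19 and 15, against 9, 6, 5, 5, 5 and 6 as reported. The 3 in FIH null cells were Hox genes (fry adjusted p = 2.41e-06), NRF2 targets (0.00531) and cartilage and bone markers (0.00704), the last not called by camera. All other lists reported for FIH null cells did not pass with fry (adjusted p from 0.0888 to 0.416). The replicate number as a block gave 890, 5343, 5015, 4553, 5453 and 2810 genes and the reported number of lists in each comparison.

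Leaving out 1 array at a time gave 353 to 951 genes for FIH null, 3606 to 5444 for VHL null and 3491 to 4669 for double null against wild type. It gave 3099 to 4208 for double null against VHL null, 3941 to 5180 for double null against FIH null, 1646 to 2529 for the interaction (lowest without FIH null replicate 1), and 2068 to 2653 and 187 to 404 for VHL and FIH loss in both backgrounds. The FIH count was 382 without wild type replicate 1, 379 without wild type replicate 2, 353 without FIH null replicate 1 and 391 without FIH null replicate 2, and FIH loss in both backgrounds gave 213, 194, 187 and 196. Lists numbered 5 to 8 for FIH null (5 without FIH null replicate 2), 5 to 6 for VHL null and 4 to 7 for double null against wild type. They numbered 4 to 8 for double null against VHL null (8 without double null replicate 2), 5 to 5 for double null against FIH null and 6 to 9 for the interaction.

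Results whose tested direction reversed were Ntng1 in FIH null cells without the filter (-0.61), where another probe set represents it, oxidative phosphorylation in VHL null cells with quantile normalization (-0.0434) and with scaling to hybridization controls (-0.30). With that scaling so did oxidative phosphorylation (-0.18), cell cycle genes (-0.19), Aurkb (-0.0269) and Me1 (-0.027) in FIH null and Cox5a (-0.0419) in VHL null cells. The mean log2 change of a list itself turned sign in 14 evaluations, the 4 reversed ones, 2 of those that no longer passed and 8 of those counted as kept. With scaling to hybridization controls these others were, in FIH null cells, glycolysis (-0.0358), other hypoxia-inducible genes (-0.145), amino acid deprivation genes (-0.17) and NRF2 targets (-0.111). In double null cells against wild type they were p53 targets (-0.0304) and contractile genes (-0.269), and in the interaction oxidative phosphorylation (0.00277) and glycolysis (0.0979). The glycolysis interaction, which did not pass, also turned without VHL null replicate 1 (0.00181) and without double null replicate 2 (0.117).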

Other observations

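The genes of the first paragraph were chosen after their values were seen, while the tests of chromosomes were set before their results were seen. Imprinted genes did not pass as a list. Between double null and VHL null cells, where 37.7% of all genes changed, 5 of 17 were higher and 7 lower (mean -0.09), and those named here were picked from them. Dlk1 and Meg3, neighbours in one imprinted cluster, read 30846 ± 1245 and 8684 ± 186 in VHL null and 7166 ± 1192 and 3522 ± 872 in double null cells (log2 changes -2.11 and -1.32, adjusted p = 3.12e-08 and 1.54e-05). Rian of the same cluster fell by 1.51 (adjusted p = 1.17e-05). The growth inhibitor gene Cdkn1c fell from 8418 ± 701 to 1416 ± 272 (adjusted p = 3.44e-08), while Ndn rose from 899 ± 90.1 to 15437 ± 2037 (adjusted p = 1.24e-09) and Plagl1 from 8322 ± 417 to 28042 ± 4637 (adjusted p = 2.68e-07). Ptgs2, which encodes a cyclooxygenase, read 10430.3 ± 1010.2 in wild type, 8293 ± 109 in FIH null, 41734 ± 2753 in VHL null and 35718 ± 1171 in double null cells. It rose with VHL loss in both backgrounds (log2 changes 2.00 and 2.10, adjusted p = 1.13e-08 and 4.04e-09). The adhesion gene Vcam1 fell in VHL null cells from 8211 ± 176 to 1860.5 ± 229 (adjusted p = 1.94e-07). Idh1, the cytosolic isocitrate dehydrogenase gene, fell with VHL loss in both backgrounds, from 14596 ± 648 to 5999 ± 160.3 (adjusted p = 3.29e-06) and from 13773 ± 23.5 to 6184 ± 1099 (adjusted p = 3.63e-06).

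Genes of one chromosome shifted together, and a change in the number of copies of whole chromosomes in these immortalized lines was tested as a hypothesis. With each chromosome parted in the middle of its gene order, the medians of both parts correlated across 20 chromosomes in all 6 comparisons. The correlation was lowest for double null against FIH null cells (r = 0.657, permutation p = 0.003, adjusted 0.003; rho = 0.415, permutation p = 0.072; r = 0.168 without chromosomes 9 and 18, on which it rests). In the other comparisons r ran from 0.697 to 0.971, from 0.569 to 0.947 without the 2 farthest chromosomes, with adjusted permutation p from 2e-05, the smallest here, to 0.00096. Local clusters of regulated genes are argued against as the whole cause by the correlation of both parts (permutation p = 0.003 in the comparison with the lowest r). Expression level and gene length are argued against by the spread of medians that remained after correction for them (permutation p = 0.0005, the smallest that 2000 shuffles can give). A change of dosage is consistent with r = 0.657, but no measure of DNA was used here.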
